A study of Mus musculus with 4 samples.

How the data were processed

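Plantaris muscle of 28-month-old mice was profiled by single-cell RNA sequencing in 4 libraries, 2 from satellite cell-depleted mice (tamoxifen) and 2 from satellite cell-retained mice (oil), 96 hours after synergist ablation. Per the labels, muscles were digested with collagenase and dispase, and cells were sorted with gates that remove debris, doublets and DAPI-positive cells, loaded on the 10x 3' version 3 chemistry and processed in a single batch. The deposited values are UMI counts per gene and barcode, made by the authors with Cell Ranger 7.1.0 on mm10 and not normalized, per the submitters' processing notes and the file headers. The barcodes had been called as cells before deposit; whether counting used the strand or intronic reads is not given in the sources used here. Groups were taken from the sample titles. Each of the 32285 genes was matched to GENCODE vM21 by Ensembl identifier (32158 matched), which gave the coordinates of all 104 named genes.

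The files held 19275 barcodes and 282647071 UMIs. Barcodes with at least 300 genes and at most 20% mitochondrially encoded UMIs were kept (18647; 628 removed, or 125, 143, 160 and 200 per library). Doublets were scored per library with simulated doublets (Scrublet, as in scanpy), and the highest scores were removed at 0.8% for each 1000 barcodes (697 removed, or 172, 184, 186 and 155), which left 17950 cells. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes gave 30 principal components, a graph of 20 neighbors and Leiden clusters at resolution 1.0 (23 clusters). Clusters were named from 15 marker lists fixed before the data were examined: a class needed at least 3 markers detected in 20% of the cluster's cells, and the 10 leading genes by fold were read against the name. The cluster that held the myogenic cells also held other cells and was clustered once more. Clusters that met no name stayed unnamed, 1 of them led by mitochondrially encoded genes. B cells, mast cells, lymphatic endothelial cells and erythroid cells formed no cluster.

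Cells are not replicates. Counts were summed per library and class, for classes with at least 20 cells in each library, and tested with edgeR (quasi-likelihood, TMM scaling, filterByExpr) with the library as the replicate. P-values were adjusted by Benjamini-Hochberg over the genes of a class, and an adjusted p under 0.05 is called here. Log2 differences are depleted over retained, with standard errors (SE). The SE was worked back from the edgeR test, as the absolute log2 difference over the square root of its F statistic. Cell numbers per class were tested with edgeR with the log of all cells of a library as offset. Whether the difference between depleted and retained libraries was the same in fibrogenic cells and macrophages was tested as an interaction, with the library as a block since both sums come from the same library. Shares carry exact binomial 95% intervals; a count of 0 allows a share of up to 3 cells. For shares of cells with a UMI each cell was also thinned to 2000 UMIs.

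The 25 gene lists were fixed before the data were examined: collagens, matrix glycoproteins and proteoglycans, collagen processing and crosslinking, matrix proteases and inhibitors, chemokines and cytokines, TGF-beta and myofibroblast genes, growth factor ligands, complement, cell cycle, interferon response, inflammatory macrophage genes, resident and alternatively activated macrophage genes, phagocytic and lipid-handling genes, MHC class II, endothelial activation and angiogenesis, senescence-associated genes, glycolysis, oxidative phosphorylation, mitochondrially encoded genes, dissociation and immediate-early stress genes, neutrophil genes, erythroid genes, myofiber genes, satellite cell and myoblast genes, and T and NK cell genes. Lists with at least 3 tested genes were tested with camera (limma) with a preset correlation of 0.01, and again with the correlation estimated and with fry; p-values were adjusted over the lists of a class. The preset correlation is low, so a list whose genes vary together between mice can be called too readily. The estimated values are given beside each call for that reason. With an estimated correlation or fry, the test draws on the few degrees of freedom that 4 libraries leave, so calls are hard to reach. Endothelial activation genes in fibrogenic cells had an estimated correlation of -0.069, below the preset one, yet the camera p went from 0.000137 to 0.0558. A call lost there therefore does not decide whether its list differs.

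Genes were named by a rule written before the data were examined: the satellite cell genes Pax7, Myf5, Myod1 and Myog; called genes with the largest differences, a mean of at least 20 CPM and both libraries of 1 group above both of the other; up to 4 members with the smallest p of each called list; and 3 members of the collagen, matrix glycoprotein, chemokine and macrophage lists whether called or not. Genes that only DESeq2 called, and Cxcl9 in the interaction, were named after their values were seen. Genes at under 5% of their level in another class were marked as prone to come from other cells (1000 of 13941 in fibrogenic cells, 998 of 12365 in macrophages and 105 of 6075 in endothelial cells). Close paralogs (the H2, Ifit and hemoglobin genes, Hspa1a and Hspa1b) can share reads, and Col4a1 and Col4a2 overlap at their starts, so reads there depend on how strand was used.

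On simulated data with 200 changed genes in 5 draws per class, edgeR found 59.4% of 2-fold and 91.8% of 4-fold changes in fibrogenic cells (6 false calls on average), 64% and 92.6% in macrophages (8.8), and 15.8% and 83% in endothelial cells (3). In T and NK cells it found 30.4% and 92.8% (6), in dendritic cells 19.4% and 82% (4), in myofiber barcodes 33.8% and 87.6% (5) and in neutrophils 1.6% and 46.2% (1.6). The interaction found 26% and 86.8% (4.6). These counts were drawn gene by gene with the dispersion of the fitted trend. Real genes that vary more than the trend, or together within a library, can be found less often. Camera found a list of 20 members shifted by 0.5 in 5 of 5 draws and called 0 of 100 unshifted lists. The members were drawn as independent genes, so this gives no false-call rate for lists whose genes vary together. The class test found an 8-fold fall of myogenic cells in 12 of 50 draws. Libraries of a pair differed beyond sampling noise (chi-square per degree of freedom 67.3 to 169), so none was a copy of another.

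Alternatives fixed before the data were examined were DESeq2 size factors, no filter on low counts, the DESeq2 Wald test, equal cells and depth per class, genes prone to come from other cells left out, a stricter cell filter (800 genes, 10% mitochondrial), doublets kept, resolutions of 0.5 and 2.0, the replicate number as a block, other offsets for cell shares, and each library left out in turn. Chosen after seeing the data were equal numbers of cells of each cluster in every library (in dendritic, endothelial and T and NK cells, each a single cluster, only a draw of 39, 34 and 24 cells per library), fibrogenic barcodes with over 10 UMIs of macrophage and dendritic markers left out, and myofiber barcodes left out of the shares. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9. Mural, tenocyte, glial and myogenic cells were too few for gene tests. Sequencing reads were not used here.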

Results

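Single-cell RNA sequencing was used to profile the plantaris muscle of 28-month-old mice 96 hours after mechanical overload, in which the gastrocnemius and soleus were removed on both sides so that the plantaris carried more load. The mice carried a tamoxifen-inducible Cre under the control of Pax7, the marker of satellite cells (the stem cells of muscle), together with a diphtheria toxin A allele, so that tamoxifen kills cells that express Pax7. The 2 libraries called depleted here came from mice given 2 mg of tamoxifen a day for 5 days, and the 2 libraries called retained from mice given oil, with a washout of 2 weeks before surgery in both. Tamoxifen itself differed between the groups in the same way as the depletion. The libraries held 4767 and 4934 barcodes (depleted 1 and 2) and 4976 and 4598 barcodes (retained 1 and 2). Their total counts of unique molecular identifiers (UMIs) were 75545942, 69801877, 67385677 and 69913575 in the same order, with medians of 11865, 9659.5, 10729 and 9234.5 UMIs per barcode. After filtering, 4470, 4607, 4630 and 4243 cells remained, 17950 in all. The labels do not say whether each library came from 1 animal. P-values of single genes and cell classes therefore measure only the spread between these samples, which may be technical. P-values of lists from camera with the preset correlation compare list members with the other genes. They can therefore be very small with 2 libraries per group and do not measure that spread. An exact permutation test of 2 against 2 libraries cannot go below p = 0.33, and tests therefore came from edgeR models that share their spread across genes or cell classes.

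The first question was whether satellite cells were fewer in the depleted libraries. Pax7 (ENSMUSG00000028736, mm10 chromosome 4, 139737062 to 139833528, minus strand), the transcription factor of satellite cells, had 6 and 1 UMIs in the depleted libraries and 62 and 17 in the retained libraries. Cells with a Pax7 UMI made up 0.0447% (2 cells; exact binomial 95% interval 0.00542 to 0.162) and 0.0217% (1 cell; 0.00055 to 0.121) of the depleted libraries, against 0.756% (35 cells; 0.527 to 1.05) and 0.141% (6 cells; 0.0519 to 0.308) of the retained ones. Myf5 (ENSMUSG00000000435, chromosome 10, 107482908 to 107486134, minus strand), an early myogenic factor, followed with 3 and 1 UMIs against 197 and 29. Myod1, a factor of activated satellite cells and myoblasts (ENSMUSG00000009471, chromosome 7, 46376474 to 46379099, plus strand), had 162 and 128 against 582 and 170 UMIs. Myog, a factor of differentiating myoblasts (ENSMUSG00000026459, chromosome 1, 134289989 to 134292548, plus strand), had 70 and 43 against 1819 and 77 UMIs. The counts of retained library 1 exceeded those of retained library 2 for each of these 4 genes. Shares of cells with a Myod1 UMI overlapped between the groups (2.17% and 2.08% depleted, 2.51% and 1.79% retained). So did those of Myog (1.14% and 0.673% against 1.62% and 0.660%). The myogenic class, described below, held 31 and 0 of the Myod1 UMIs in the depleted and 470 and 51 in the retained libraries.

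Macrophages, which should lack Pax7, gave the background. A Pax7 UMI was found in 0 of 1602 and 0 of 1900 macrophages of the depleted libraries, which allows shares of up to 0.187% and 0.158%, and in 1 of 2124 (0.0471%) and 0 of 1627 (up to 0.184%) of the retained libraries. Median depth was 13424, 11959, 12835 and 12959 UMIs in macrophages and 11973.5, 9830, 10966.5 and 9591 UMIs in all cells. The number of macrophages sets these limits. By themselves they are too wide to say whether the Pax7 shares of the depleted libraries and of retained library 2 are background. By class, 34 of the 35 Pax7 cells of retained library 1 were in the myogenic class, which Pax7 helped to name. So were all 6 of retained library 2 and both of depleted library 1, and the 1 of depleted library 2 was a myofiber barcode. In retained library 2 those 6 cells held all 17 Pax7 UMIs, and 5 of its 7 myogenic cells held a Myf5 UMI. RNA scattered over droplets would also fall in other classes, so these values argue against background there, though on few cells. Myf5 also helped to name the class, so the place of both genes in it is partly built in, which weakens this argument. The 2 cells of depleted library 1 held all 6 of its UMIs, too few cells to decide. With each cell thinned to 2000 UMIs, which left out 417, 749, 754 and 619 shallower cells, Pax7 was found in 0 of 4053 and 0 of 3858 depleted cells (up to 0.074% and 0.0778%) and in 10 of 3876 (0.258%) and 3 of 3624 (0.0828%) retained cells. For Myog in retained library 1, 1.84% of macrophages and 1.44% of other cells had a UMI, at median depths of 12835 and 4962 UMIs. Thinned to 2000 UMIs, the order turned: 0.474% of macrophages (10 of 2109) against 0.849% of the other cells (15 of 1767). The Myog share there therefore includes background, and these values do not say how much. Of its 1819 UMIs, 1738 lay in 18 myogenic cells. Intervals and limits cover counting error only.

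The myogenic class, named from 8 fixed markers, held 3 and 5 cells in the depleted libraries and 64 and 7 cells in the retained ones (0.0878% ± 0.0293 against 0.774% ± 0.861, mean ± SD, n = 2 each). The 5 myogenic cells of depleted library 2 carried a UMI of 0 of the 8 markers, whereas 2 of the 3 cells of depleted library 1 and all 64 and all 7 cells of the retained libraries carried at least 1. Cells with at least 2 markers numbered 2 and 0 in the depleted and 61 and 7 in the retained libraries. The ratios that follow count all cells of the class, the 5 without a marker included. Modelled on the cell counts of all classes with edgeR, the log2 ratio of depleted over retained was -3.10 ± 1.15 (SE; adjusted p = 0.267 over 11 classes), and the class was not called. Most of the difference rested on retained library 1: without it the ratio was -0.89. In simulated data of this size, an 8-fold fall of the myogenic class was called in 12 of 50 draws.

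**Figure D1:**
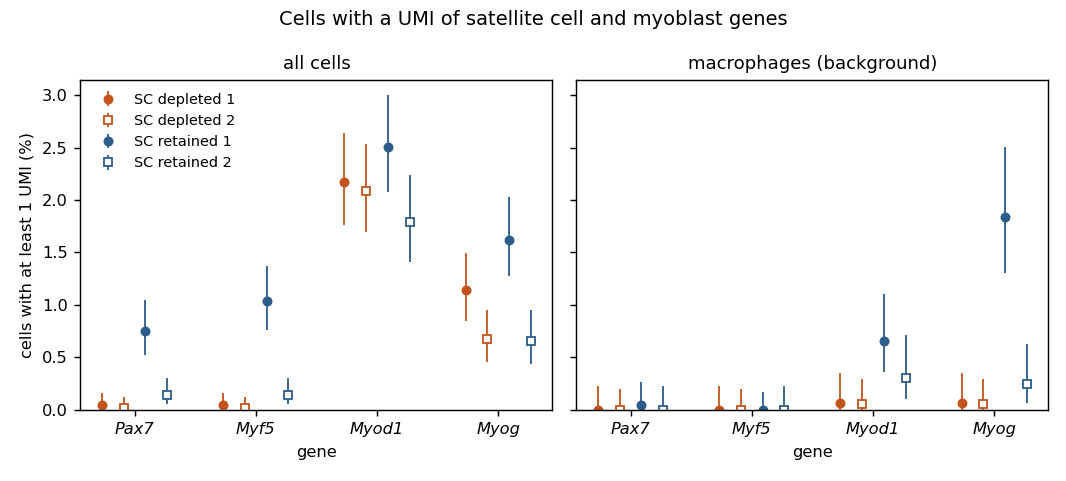
Percent of cells with a UMI of Pax7, Myf5, Myod1 and Myog in each library, in all cells and in macrophages, with exact binomial 95% intervals. Pax7 was found in 0.756% and 0.141% of the cells of the retained libraries and in 0.0447% and 0.0217% of those of the depleted libraries.

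The next question was whether the make-up of the mononuclear cells differed between the groups. Macrophages were the most frequent class, at 38.5% ± 3.82 of cells in the depleted and 42.1% ± 5.32 in the retained libraries (mean ± SD, n = 2 each, here and below). Fibrogenic cells, the matrix-producing mesenchymal cells of muscle, made up 23.4% ± 9.61 against 15.3% ± 0.0262. Depleted library 1 held 30.2% fibrogenic cells (95% interval 28.9 to 31.6) and depleted library 2 held 16.6% (15.6 to 17.8), the latter near the 15.4% and 15.3% of the retained libraries. Neutrophils made up 10.8% ± 4.49 against 17.8% ± 5.64 and dendritic cells 2.88% ± 2.84 against 5.39% ± 1.15. Barcodes led by genes of muscle fibers such as Acta1 and Mylpf, called myofiber barcodes here, made up 18.4% ± 0.245 against 11.03% ± 2.86. They held a median of 3171.5 UMIs, and a median of 0.0503% of these were mitochondrially encoded. T and NK cells made up 0.540% ± 0.00406 against 1.57% ± 1.24, with 104 cells in retained library 2 and 32 in retained library 1.

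None of the 11 classes was called by edgeR, which gave 1 class, the myogenic one, at an unadjusted p under 0.05. The log2 ratios of depleted over retained were 0.61 ± 0.75 (SE) for fibrogenic cells (adjusted p = 0.682) and -0.13 ± 0.72 for macrophages (adjusted p = 0.986). They were -0.71 for neutrophils, 0.74 for myofiber barcodes, -0.90 for dendritic cells (adjusted p = 0.682 for each) and -1.54 for T and NK cells (adjusted p = 0.613). With immune cells left out of the denominator the fibrogenic ratio was 0.07 and the myofiber ratio 0.27, and with the stricter cell filter the neutrophil ratio was 0.05. The rarer classes had 0.84 (mural), 0.52 (tenocyte), 0.06 (endothelial) and -0.02 (glial). The dendritic class was named on 3 detected markers and depended on the resolution. With finer clusters it held 14, 106, 115 and 115 cells (depleted 1 and 2, retained 1 and 2), against 39, 225, 287 and 194 in the main setting. Without each library in turn the fibrogenic ratio ranged from 0.12 (without depleted library 1) to 0.98 (without depleted library 2), the neutrophil ratio from -1.21 to -0.34 and the myofiber ratio from 0.50 to 1.03. The dendritic ratio ranged from -2.62 (without depleted library 2) to -0.14 (without depleted library 1), and the T and NK ratio from -2.18 (without retained library 1) to -0.36 (without retained library 2). For some classes, libraries of 1 group lay further apart than the counting error. Endothelial cells made up 2.95% (2.48 to 3.49) and 0.738% (0.512 to 1.03) of the depleted libraries. In the retained ones they made up 2.70% (2.25 to 3.21) and 0.848% (0.595 to 1.17), so library 1 was higher in both groups. A further 1.95%, 2.69%, 3.93% and 3.09% of cells (depleted 1 and 2, retained 1 and 2) stayed without a name. Cells had been sorted after digestion with gates against debris, doublets and dead cells, and that sort sets part of every share.

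**Figure D2:**
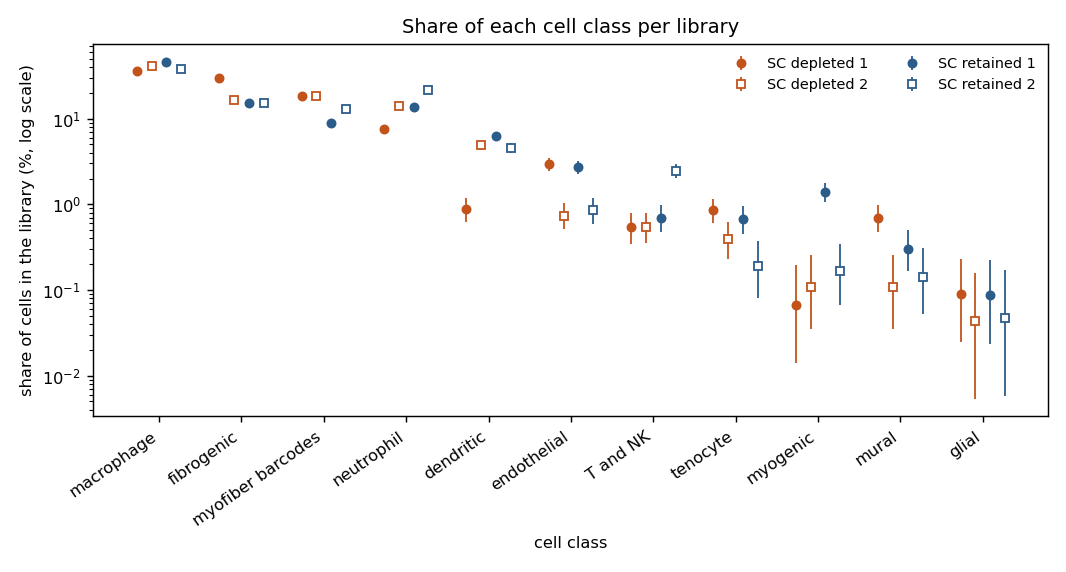
Percent of cells of each class in the 4 libraries, with exact binomial 95% intervals. Fibrogenic cells ranged from 15.3% to 30.2% and macrophages from 35.8% to 45.9% of the cells of a library.

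The study's title concerns a circuit between immune cells and fibrogenic cells, and the next comparison asked which genes of fibrogenic cells differed between the depleted and the retained libraries. Genes of major histocompatibility complex (MHC) class II, which present antigen to T cells, fell in the fibrogenic sums of the depleted libraries: 7 of 7 measured members were lower, with a median log2 difference of -1.62 (depleted over retained; camera, adjusted p = 9.82e-52, or adjusted p = 0.316 with an estimated correlation). Cd74 (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652, plus strand), the chaperone of class II molecules, stood at 7.15 and 14.2 CPM (counts scaled by library size) in the depleted and 97.5 and 75.0 CPM in the retained libraries (log2 -3.00 ± 0.34, adjusted p = 0.737). H2-Aa (chromosome 17, 34282744 to 34287823, minus strand), a class II chain, stood at 1.64 and 6.77 against 41.9 and 32.7 CPM. Interferon response genes, the antiviral program, fell by a median of 0.37 on the log2 scale (18 of 21 lower; adjusted p = 2.49e-10, or adjusted p = 0.385 with an estimated correlation). Among them were Rsad2, an antiviral enzyme (log2 -1.07 ± 0.20), Ifit3 (-0.70 ± 0.25) and Isg15 (-0.57 ± 0.20). Genes of inflammatory macrophages fell by a median of 0.64 (17 of 19 lower; adjusted p = 1.21e-10, or adjusted p = 0.316 with an estimated correlation). The cytokine Il1b stood at -0.98 ± 0.21, the chemokine Ccl3 at -1.26 ± 0.28 and the inflammasome sensor Nlrp3 at -0.94 ± 0.23. The nitric oxide synthase Nos2, of the same list, went the other way (2.59 ± 0.53, with 46 and 42 against 2 and 10 UMIs).

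Signals of other cells moved with these groups. All 7 MHC class II members, 14 of the 19 inflammatory macrophage members and 0 of the 21 interferon members measured in fibrogenic sums were at under 5% of their level in another class. Fibrogenic barcodes with over 10 UMIs of 21 macrophage and dendritic markers made up 23.0% and 31.8% of the class in the depleted and 28.1% and 46.9% in the retained libraries. These barcodes held 57.9% and 67.5% of the class II UMIs of the depleted and 80.9% and 87.3% of those of the retained libraries. The bound is a fixed number of UMIs, which deeper barcodes cross more readily. The shares followed the order of median fibrogenic depth (25364 and 35721 UMIs in the depleted, 29122 and 46679 in the retained libraries). Depth and immune RNA are therefore not told apart in these shares, and leaving such barcodes out can also remove deeper ones unequally. The 2% of fibrogenic barcodes with the most UMIs of 4 class II genes (14 and 13 barcodes) held 68.8% and 68.7% of these UMIs in the retained libraries, and 53.7% and 32.0% in the depleted ones (27 and 15 barcodes). The median barcode held 0 and 1 of these UMIs in the depleted and 2 and 2 in the retained libraries. Without the barcodes rich in immune markers, a setting chosen after seeing the data, the class II median was -1.40 (6 of 6 lower), the interferon median -0.70 (21 of 21 lower) and the inflammatory median -0.22. The inflammatory list was no longer called without its genes at under 5% of their level in another class (median -0.17, adjusted p = 0.222). Myofiber genes rose in the same sums by a median of 1.25 (13 of 14 higher; adjusted p = 9.45e-24, or adjusted p = 0.316 with an estimated correlation), with all 14 at under 5% of their level in another class. The 2% of fibrogenic barcodes with the most UMIs of 8 myofiber genes held 64.0% and 50.1% of these UMIs in the depleted libraries (27 and 15 barcodes) and 39.3% and 9.98% in the retained ones, while the median barcode held 3 and 4 against 2 and 3. Skeletal actin Acta1 (chromosome 8, 123891769 to 123894751, minus strand) stood at 114 and 84.0 against 46.0 and 36.1 CPM. Leaving out depleted library 2 moved the class II median to -2.61 and leaving out depleted library 1 moved the myofiber median to 0.76, while leaving out retained library 1 moved the inflammatory median to -0.42; all 4 lists kept their calls without each library in turn.

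Matrix genes, the product of these cells, gave no comparable difference. The 16 collagens split into 8 higher and 8 lower members, with a median of -0.01 (adjusted p = 0.868), and the 3 with the smallest p were Col15a1 (log2 0.50 ± 0.22), Col12a1 (-0.20 ± 0.19) and Col5a3 (0.12 ± 0.13), each with an adjusted p of 1. Matrix glycoproteins and proteoglycans rose by a median of 0.11 (17 of 21 higher; adjusted p = 0.0105, or adjusted p = 0.683 with an estimated correlation). The cartilage matrix protein Comp stood at 0.70 ± 0.21, Thbs4 at 0.45 ± 0.22 and fibromodulin (Fmod) at 0.67 ± 0.34. All 3 are markers of tenocytes (0.620% of cells in the depleted and 0.429% in the retained libraries), and Comp and Fmod were at under 5% of their level in another class. That call was lost without depleted library 2 (-0.04, adjusted p = 0.858) or retained library 2 (0.03, adjusted p = 0.415), with the same cluster make-up in every library (0.03, adjusted p = 0.272), without the barcodes rich in immune markers (-0.04, adjusted p = 0.918) and without genes at under 5% of their level in another class (0.09, adjusted p = 0.117). It was 0.24 without depleted library 1 and 0.22 without retained library 1. Collagen processing (median 0.04, adjusted p = 0.295), matrix proteases and inhibitors (0.02, 0.323), TGF-beta and myofibroblast genes (0.10, 0.156) and growth factor ligands (0.08, 0.319) were not called.

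The remaining fibrogenic lists that were called lost their calls without 1 or more of the single libraries. Endothelial activation genes rose by 0.34 (11 of 14 higher; adjusted p = 0.000684, or adjusted p = 0.349 with an estimated correlation). P-selectin (Selp) stood at 32 and 24 against 3 and 2 UMIs. That call was lost without retained library 2 (0.34, adjusted p = 0.213) and without genes at under 5% of their level in another class (0.04, adjusted p = 0.0618), with the same cluster make-up (0.18, adjusted p = 0.159) and without the barcodes rich in immune markers (0.20, adjusted p = 0.156). Glycolysis genes rose by 0.09 (14 of 16; adjusted p = 0.0439, or adjusted p = 0.758 with an estimated correlation). The glucose transporter Slc2a1 stood at 0.33 ± 0.18 and the lactate transporter Slc16a3 at 0.38 ± 0.25. Immediate-early stress genes, which respond to dissociation, fell by 0.11 (18 of 20 lower; adjusted p = 0.00958, or adjusted p = 0.683 with an estimated correlation). The phosphatase Dusp1 stood at -0.31 ± 0.12 and the transcription factor Atf3 at -0.27 ± 0.13. The glycolysis call was lost without depleted library 2 (-0.01, adjusted p = 0.716) or retained library 1 (0.02, adjusted p = 0.705), with no filter on low counts (adjusted p = 0.0712), without genes at under 5% of their level in another class (adjusted p = 0.0618) and with the same cluster make-up (adjusted p = 0.13). The stress call was lost without depleted library 2 (-0.03, adjusted p = 0.716) or retained library 1 (-0.11, adjusted p = 0.177). Without depleted library 1 the medians were 0.21 (glycolysis) and -0.24 (stress), and without retained library 2 the glycolysis median was 0.19.

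For chemokines and cytokines the median was 0.03 while the mean was -0.29 and the test pointed down (14 higher, 13 lower; adjusted p = 0.0277, or adjusted p = 0.487 with an estimated correlation). The neutrophil attractant Cxcl5 stood at -1.23 ± 0.42 and Cxcl16, a ligand of T cells, at 0.43 ± 0.15. Complement genes fell by a median of 0.15 (8 of 14 lower; adjusted p = 0.0277, or adjusted p = 0.707 with an estimated correlation). Properdin (Cfp) stood at -1.29 ± 0.31 and the opsonin subunit C1qb at -0.80 ± 0.27, both genes of macrophages at under 5% of their level in another class, and C2 at 0.69 ± 0.28. Neutrophil genes fell by 0.28 (7 of 8 lower; adjusted p = 0.0402, or adjusted p = 0.683 with an estimated correlation), with the receptor Csf3r at -0.90 ± 0.37 and all 8 at under 5% of their level in another class. The chemokine call was lost without depleted library 2 (-0.07, adjusted p = 0.165) or retained library 1 (-0.03, adjusted p = 0.653). The complement call was lost without the same libraries (-0.07, adjusted p = 0.705; 0.13, adjusted p = 0.319), and the neutrophil call without depleted library 2 (0.23, adjusted p = 0.705) or retained library 2 (0.37, adjusted p = 0.667). Without depleted library 1 the medians were -0.26 (chemokines), -0.29 (complement) and -0.92 (neutrophil genes); without retained library 2 they were -0.18 and -0.27 for the first 2, and without retained library 1 the neutrophil median was -0.79. Each of these 3 calls was also lost with doublets kept (adjusted p = 0.25, 0.367 and 0.185) and without the barcodes rich in immune markers (0.559, 0.235 and 0.0786). Without genes at under 5% of their level in another class the chemokine and complement calls were lost and their medians were 0.09 (13 higher, 4 lower; adjusted p = 0.342) and 0.14 (6 higher, 2 lower; adjusted p = 0.117).

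The other fibrogenic lists were not called: cell cycle (median -0.07), resident macrophage genes (-0.13), phagocytic and lipid-handling genes (-0.03), senescence-associated genes (0.13), oxidative phosphorylation (0.02), mitochondrially encoded genes (-0.06), erythroid genes (2.17), satellite cell and myoblast genes (-0.15) and T and NK cell genes (0.31). Median, mean and test differed in sign for collagens, growth factor ligands and phagocytic genes besides the chemokines. In total 11 of 25 lists were called, 4 up and 7 down, and 0 with an estimated correlation or with fry; 2 were called without genes at under 5% of their level in another class and 7 without the barcodes rich in immune markers. Adjusted over the list alone, edgeR called 7 of 7 class II genes (all lower), 1 interferon gene (lower), 4 inflammatory genes (1 higher, 3 lower), 1 endothelial activation gene and 4 myofiber genes (all higher), 17 in all. Over all 13941 genes edgeR called 0, with 375 at an unadjusted p under 0.05 (168 higher, 207 lower). With the replicate number as a block edgeR called 53 (31 higher, 22 lower), and without it DESeq2 called 14 (5 higher, 9 lower). Of those 14, Cd74, H2-Eb1, H2-DMb1 and Acta1 were at under 5% of their level in another class, so they need not belong to fibrogenic cells. The interferon gene Rsad2 was not at such a level, and the other genes DESeq2 called were on none of the 25 lists. Leaving out depleted 1, depleted 2 or retained 1 gave 1, 5 and 1 calls.

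Macrophages were compared next, as the largest immune class. Interferon response genes fell in the depleted libraries, with 20 of 21 members lower and a median log2 difference of -0.67 (camera, adjusted p = 6.4e-39, or adjusted p = 0.531 with an estimated correlation). Isg15 (ENSMUSG00000035692, chromosome 4, 156199424 to 156200818, minus strand), a ubiquitin-like antiviral protein, stood at 123 and 93.9 CPM in the depleted and 262 and 297 CPM in the retained libraries (log2 -1.35 ± 0.17, adjusted p = 0.188). Ifit2 (-1.31 ± 0.19), the GTPase Irgm1 (-0.81 ± 0.13) and Rsad2 (-0.86 ± 0.14) lay lower as well, and for 17 of the 21 genes both depleted libraries were below both retained ones. MHC class II genes fell by a median of 1.54 (9 of 9 lower, each with both depleted below both retained libraries; adjusted p = 1.72e-23, or adjusted p = 0.531 with an estimated correlation). Cd74 stood at 1394 and 3199 against 5836 and 7702 CPM and the chain H2-Ab1 at 255 and 671 against 1353 and 1757 CPM. The chemokine Cxcl9 (chromosome 5, 92321347 to 92328079, minus strand), which interferon induces and which attracts T cells, stood at 0.993 and 0.962 against 11.01 and 5.69 CPM (log2 -3.10 ± 0.40, adjusted p = 0.204), at under 5% of its level in another class.

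Genes of resident and alternatively activated macrophages rose by a median of 0.43 (17 of 18 higher; adjusted p = 2.39e-11, or adjusted p = 0.531 with an estimated correlation). Retnla, a marker of alternative activation (chromosome 16, 48842551 to 48844461, plus strand), stood at 29.8 and 74.2 against 8.55 and 17.6 CPM (log2 2.02 ± 0.47), the carbonyl reductase Cbr2 at 0.64 ± 0.13, the growth arrest ligand Gas6 at 0.63 ± 0.16 and the clotting factor subunit F13a1 at 0.74 ± 0.21. Cluster sizes varied between libraries of the same group. Cluster 2, led by C1qa, Ccl8, Mrc1 and Cbr2, held 29.5% and 26.1% of the macrophages of the depleted libraries and 16.8% and 16.5% of those of the retained ones. Cluster 1, led by Cd74 and H2-Aa, held 21.1% and 15.7% against 21.6% and 37.8%. Cluster 5, with Arg1, Cxcl3 and Cxcl2 among its leading genes, held 9.74% and 32.2% against 16.9% and 8.91%. The largest cluster was a different one in each of the 4 libraries. A further cluster, led by Rsad2, Isg15 and Ifit3, held 4.74% and 2.89% against 6.87% and 13.1%. These lists therefore include genes that define clusters, and cluster sizes were not tested. With the same number of cells of each cluster in every library, a setting chosen after seeing the data, the medians were -0.18 for interferon genes (16 of 21 lower), -1.11 for class II genes (9 of 9 lower) and 0.24 for resident genes, and Rsad2 turned to 0.25. The 3 lists kept their calls there and without each library in turn, where the medians ranged from -0.77 to -0.53, from -2.26 to -1.06 and from 0.32 to 0.74, the last without retained library 1.

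Inflammatory macrophage genes rose by a median of 0.15 (15 of 20 higher; adjusted p = 0.0055, or adjusted p = 0.651 with an estimated correlation). The cytokine Il1a stood at 1.10 ± 0.24, the neutrophil attractant Cxcl2 at 0.45 ± 0.16 and the receptor antagonist Il1rn at -0.40 ± 0.20. The chitinase-like Chil3 stood at 816 CPM in depleted library 1 and at 86.4, 75.1 and 54.5 CPM in the other libraries. Glycolysis genes rose by 0.30 (16 of 16 higher; adjusted p = 5.88e-05, or adjusted p = 0.651 with an estimated correlation). The hexokinase Hk1 stood at 0.41 ± 0.14 and the pyruvate kinase Pkm at 0.31 ± 0.17. Mitochondrially encoded genes fell by 0.26 (13 of 13 lower; adjusted p = 4.3e-05, or adjusted p = 0.651 with an estimated correlation), with mt-Nd5 at -0.38 ± 0.17 and mt-Co3 at -0.27 ± 0.14. Collagen processing genes rose by 0.16 (14 of 16 higher, 12 of the 16 at under 5% of their level in another class; adjusted p = 0.0055, or adjusted p = 0.651 with an estimated correlation). The lysyl hydroxylase Plod1 stood at 0.62 ± 0.12. Myofiber genes rose by 0.35 (12 of 14; adjusted p = 5.88e-05, or adjusted p = 0.651 with an estimated correlation). Mylpf stood at 0.56 ± 0.15 and parvalbumin (Pvalb) at -0.90 ± 0.29, with all 14 at under 5% of their level in another class.

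Those 5 calls depended on single libraries. The inflammatory call was lost without depleted library 2 (0.02, adjusted p = 0.121). The glycolysis call was lost without depleted library 2 (0.06, adjusted p = 0.613) or retained library 2 (0.12, adjusted p = 0.178), and the mitochondrial call without retained library 2 (-0.16, adjusted p = 0.12). The collagen processing call was lost without depleted library 2 (0.09, adjusted p = 0.35) or retained library 1 (0.13, adjusted p = 0.117), with the stricter cell filter (0.25, adjusted p = 0.0675), with coarser clusters (0.17, adjusted p = 0.26) and with the same cluster make-up (0.14, adjusted p = 0.109). The myofiber call was lost without retained library 1 (0.20, adjusted p = 0.155) and with coarser clusters (0.07, adjusted p = 0.241). Leaving out depleted library 1 moved the inflammatory median to 0.24, the collagen processing median to 0.27 and the glycolysis median to 0.48, and leaving out retained library 1 also gave a glycolysis median of 0.48. Without retained library 2 the inflammatory median was 0.36 and the collagen processing median 0.40.

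In all, 8 of 23 lists were called in macrophages, 5 up and 3 down, with 0 called at an estimated correlation or with fry; leaving out depleted library 1 gave 16. Collagens (median -0.03, led by Col14a1 at 0.90 ± 0.41), matrix glycoproteins (0.11, led by fibronectin, Fn1, at 0.81 ± 0.37) and chemokines (0.18, adjusted p = 0.0981) were not called. Among chemokines, Ccl6 stood at 0.80 ± 0.25 and the eosinophil attractant Ccl24 at 1.45 ± 0.49. Median, mean and test differed in sign for collagens, matrix proteases, TGF-beta genes, growth factor ligands, phagocytic genes and neutrophil genes. Adjusted over the list alone, edgeR called 15 of 21 interferon genes and 8 of 9 class II genes (all lower), 3 of 18 resident genes and 1 of 16 collagen processing genes (all higher), and 34 genes over all lists. Over all 12365 genes edgeR called 0, with 635 at an unadjusted p under 0.05 (283 higher, 352 lower), and DESeq2 called 65 (27 higher, 38 lower). Without retained library 1 the edgeR count was 87, without retained library 2 it was 69 and without depleted library 2 it was 1.

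**Figure D3:**
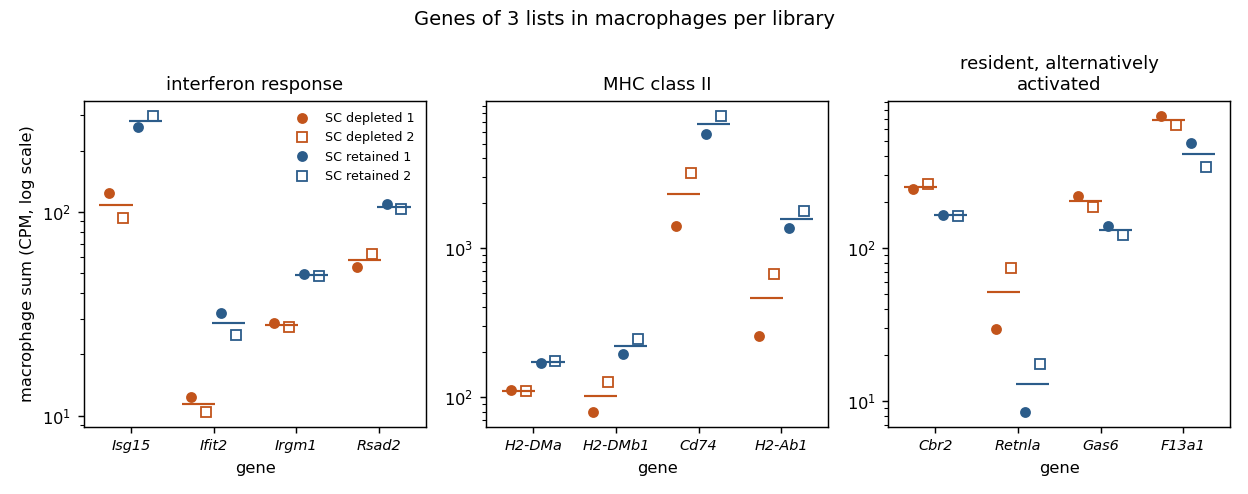
CPM of named interferon, MHC class II and resident macrophage genes in the macrophage sum of each library, on a log axis. Isg15 stood at 123 and 93.9 CPM in the depleted and at 262 and 297 CPM in the retained libraries.

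Endothelial cells were few, with 132 and 34 cells in the depleted and 125 and 36 in the retained libraries. Cell cycle genes fell by a median of 0.57 (20 of 21 lower; camera, adjusted p = 2.56e-06, or adjusted p = 0.545 with an estimated correlation). The ubiquitin-conjugating enzyme Ube2c stood at 64.4 and 49.2 against 97.5 and 126 CPM, the nucleotide reductase Rrm1 at -0.83 ± 0.34 and the topoisomerase Top2a at -0.84 ± 0.43. With equal cells and depth (34 cells per library) Ube2c turned to 0.12 and Top2a to 0.79. Endothelial activation genes fell by 0.32 (12 of 15 lower; adjusted p = 0.00707, or adjusted p = 0.497 with an estimated correlation). The venular chemokine receptor Ackr1 (ENSMUSG00000037872, chromosome 1, 173331886 to 173333750, minus strand) stood at 18.4 and 18.5 against 81.4 and 233 CPM (log2 -3.09 ± 0.57, adjusted p = 0.997) and Selp, which captures leukocytes, at -1.76 ± 0.51, while the growth factor Pgf stood at 1.34 ± 0.48. TGF-beta and myofibroblast genes fell by 0.29 (10 of 11 lower; adjusted p = 0.0149, or adjusted p = 0.497 with an estimated correlation). They were led by Acta2 and Tagln (-1.65 ± 0.54 and -1.31 ± 0.53), contractile genes of mural cells that were at under 5% of their level in another class. Matrix glycoproteins fell by 0.32 (7 of 10 lower; adjusted p = 0.00252, or adjusted p = 0.497 with an estimated correlation). Versican (Vcan) stood at 1 and 1 against 21 and 11 UMIs and biglycan (Bgn) at -2.00 ± 0.65, both among the 3 of these 10 genes that were at under 5% of their level in another class.

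The list of resident macrophage genes rose in endothelial cells by 0.26 (5 of 7 higher; adjusted p = 0.000896, or adjusted p = 0.497 with an estimated correlation). Its members furthest apart were the transcription factor Maf, at 26 and 8 against 2 and 0 UMIs, and the hyaluronan receptor Lyve1, at 103 and 69 against 2 and 22 UMIs, which lymphatic endothelium also makes. Cells with at least 3 of 5 lymphatic endothelial markers numbered 5 and 1 in the depleted and 0 and 0 in the retained libraries. Stress genes rose by 0.21 (17 of 20 higher; adjusted p = 0.00362, or adjusted p = 0.838 with an estimated correlation). Atf3 stood at 0.78 ± 0.22 and Klf6 at 0.61 ± 0.21. Myofiber genes fell by 1.02 (8 of 8 lower; adjusted p = 1.11e-05, or adjusted p = 0.545 with an estimated correlation), and Tnnt3 stood at 67.1, 70.8, 58.1 and 315 CPM (depleted 1 and 2, retained 1 and 2). All 8 were at under 5% of their level in another class, and 1 of the 36 endothelial barcodes of retained library 2 held 50.4% of the UMIs of 8 myofiber markers there. In these cells 7 of 20 lists were called, 2 up and 5 down, with 0 called at an estimated correlation or with fry, and 4 without genes at under 5% of their level in another class. Leaving out depleted library 2 gave 13 and leaving out retained library 1 gave 12. The interferon list was not called (14 of 20 higher, median 0.26, adjusted p = 0.756).

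Of the endothelial lists, cell cycle kept its call without each library in turn, at medians from -0.88 to -0.25: -0.25 without depleted library 2, -0.25 without retained library 2 and -0.88 without retained library 1. Calls were lost without depleted library 1 for matrix glycoproteins (-0.36, adjusted p = 0.909), TGF-beta genes (0.02, adjusted p = 0.419), resident genes (-0.10, adjusted p = 0.419) and stress genes (-0.03, adjusted p = 0.982). They were lost without retained library 2 for endothelial activation (-0.05, adjusted p = 0.157), TGF-beta genes (-0.13, adjusted p = 0.0652), stress genes (-0.07, adjusted p = 0.914) and myofiber genes (0.14, adjusted p = 0.926). Without depleted library 2 the medians were -0.68 (matrix), -0.45 (TGF-beta), 0.44 (resident) and 0.50 (stress). Without retained library 1 they were -0.15 (matrix), 0.67 (resident), -0.68 (activation), 0.68 (stress) and -1.71 (myofiber). The activation median was -0.19 without depleted library 1 and the resident median 0.17 without retained library 2. Calls of matrix and stress genes were also lost with doublets kept (adjusted p = 0.828 and 0.322). Adjusted over the list alone, edgeR called 5 genes over all lists. Over all 6075 genes edgeR called 0, with 160 at an unadjusted p under 0.05 (55 higher, 105 lower), and DESeq2 called 2, Ackr1 and Fgl2. Leaving out each library in turn gave 1 (depleted 1), 4 (depleted 2), 11 (retained 1) and 17 (retained 2) calls.

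In the other classes with at least 20 cells in each library, edgeR called 1 gene in all. That gene was Calca (ENSMUSG00000030669, chromosome 7, 114631478 to 114636357, minus strand), which encodes calcitonin and the calcitonin gene-related peptide, in the T and NK cell class. It stood at 722 and 876 CPM in the depleted and 6.58 and 13.1 CPM in the retained libraries (log2 6.02 ± 0.39, edgeR adjusted p = 4.9e-05, 1990 genes). The counts behind it came from 6 of 24 and 6 of 25 cells in the depleted and 1 of 32 and 3 of 104 cells in the retained libraries, with 92, 125, 1 and 11 UMIs. DESeq2 called it too, while with the stricter cell filter (4.58, adjusted p = 0.52) or with doublets kept (4.58, adjusted p = 0.0649) it was not called.

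Dendritic cells (8766 genes), myofiber barcodes (7411) and neutrophils (5838) gave 0 calls with edgeR, beside 161, 303 and 285 genes at an unadjusted p under 0.05 and 1 (Isg15), 9 and 1 (Ltf) calls with DESeq2. T and NK cells had 80 genes at an unadjusted p under 0.05. Without each library in turn the edgeR count over these classes was 85 (depleted 1), 110 (depleted 2), 104 (retained 1) and 84 (retained 2).

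Whether the difference between depleted and retained libraries was the same in fibrogenic cells and macrophages was tested with an interaction term, with the library as a block. The chemokine Cxcl9 came closest to the threshold: its log2 difference between depleted and retained was 2.64 ± 0.22 higher in fibrogenic cells than in macrophages (edgeR adjusted p = 0.0847). Of 14736 genes edgeR called 0, with 620 at an unadjusted p under 0.05, and DESeq2 called 23; without retained library 1 the edgeR count was 63, without retained library 2 it was 21 and without depleted library 2 it was 1. By lists, 10 of 25 differed between the classes with the preset correlation and 0 with an estimated one, where the lowest adjusted p was 0.745. The differences of the MHC class II genes (-0.72) and the inflammatory macrophage genes (-0.55) were below 0, that is lower in fibrogenic cells, and that of the interferon genes was above 0 (0.30). In the fibrogenic sums 7 of 7 class II and 14 of 19 inflammatory genes were at under 5% of their level in another class. The class II and inflammatory values therefore need not belong to fibrogenic cells. With the same cluster make-up, chosen after seeing the data, the interferon medians were -0.36 in fibrogenic cells and -0.18 in macrophages, the other order.

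**Figure D4:**
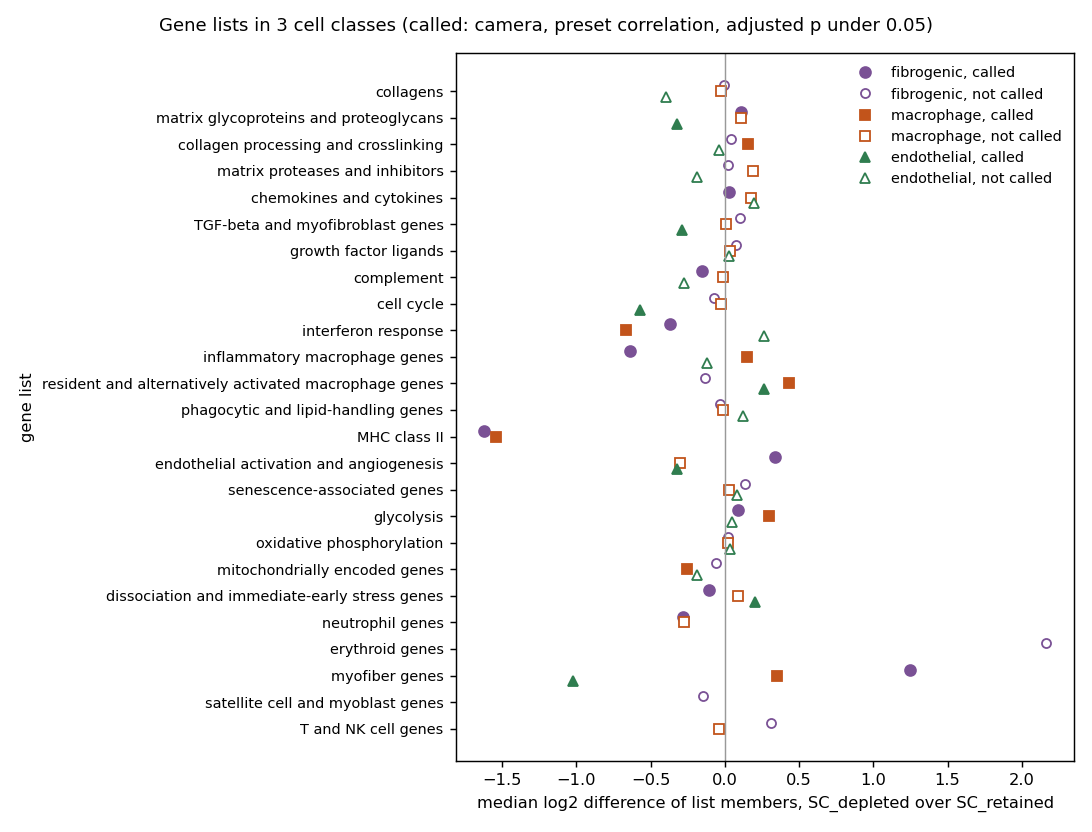
Median log2 difference (depleted over retained) of each gene list in fibrogenic cells, macrophages and endothelial cells; filled symbols mark lists called by camera with the preset correlation. MHC class II genes had medians of -1.62 in fibrogenic cells and -1.54 in macrophages, and collagens -0.01 and -0.03.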

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

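Of the tests below, the ones on barcodes rich in immune markers and on equal depth were written before their results were seen; those on myofiber barcodes, cluster make-up, single libraries, Malat1, free myofiber RNA and collagens in myofiber barcodes were chosen after results were seen.

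The difference between depleted and retained libraries was not the same in fibrogenic cells and macrophages for 10 gene lists by an interaction test (camera, preset correlation; 0 lists with an estimated correlation, lowest adjusted p = 0.745). The median log2 difference, fibrogenic minus macrophage, was -0.72 for MHC class II genes (adjusted p = 0.00157), -0.55 for inflammatory macrophage genes (5.7e-05) and 0.30 for interferon response genes (4.74e-05). It was -0.76 for resident and alternatively activated macrophage genes (0.00411) and 0.86 for myofiber genes (0.000102). It was -0.48 for chemokines and cytokines (0.0407), -0.16 for collagen processing (0.0418) and 0.23 for mitochondrially encoded genes (0.000469). For stress genes it was -0.20 (0.0383) and for the 4 erythroid genes 3.91 (0.0418). The class II value is a median over 9 genes of a joint fit, 7 of which were tested in the fibrogenic sums alone. It need not equal the difference between the class medians of -1.62 (fibrogenic) and -1.54 (macrophages). Only 1 erythroid gene was tested in the macrophage sums alone. In the fibrogenic sums 7 of 7 class II, 14 of 19 inflammatory, 11 of 15 resident, 14 of 14 myofiber and 4 of 4 erythroid genes were at under 5% of their level in another class, as were 14 of 14 myofiber and 12 of 16 collagen processing genes in macrophages. Of the chemokines and cytokines, 10 of 27 in fibrogenic sums and 10 of 26 in macrophages were. For these lists a difference between the cell types themselves is therefore not shown. The interferon medians, -0.37 in fibrogenic cells and -0.67 in macrophages, changed order with the same cluster make-up (-0.36 and -0.18). That setting was chosen after seeing the data, and the clusters were made with these genes. The interferon difference is therefore not settled either. The fibrogenic levels of the erythroid genes, 303% and 6.80% of the mean of the 4 libraries in the depleted and 81.2% and 9.14% in the retained libraries, were high in library 1 of each group.

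MHC class II genes lay lower in the fibrogenic sums of the depleted libraries, with a median of -1.62 (SD over members 0.816), and RNA of sorted immune cells could be a source, since the sort had gates against debris, doublets and dead cells and none against immune cells is given. Leaving out the barcodes rich in immune markers gave -1.40, a shift of 0.219 that lay within the bound of 0.5 written beforehand for mixed droplets not being the cause; that these barcodes held most class II UMIs had been seen by then. The 2 medians rest on 7 and 6 members, and over the 6 members in both all 6 moved toward 0, by a median of 0.86 (SD 0.453), a comparison chosen after the result, so the test was read as undecided. In myofiber barcodes, which should not make these proteins, the list stood at -2.08, as free RNA in the droplets would give. A response of the fibrogenic cells to tamoxifen or to the loss of satellite cells was not tested and stays open.

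Interferon response genes lay lower in macrophages of the depleted libraries by a median of 0.67 (SD over members 0.344). A single library does not account for it, since the median nearest 0 without each library in turn was -0.53, nor does unequal depth or cell number (-0.65 with equal cells and depth). With the same cluster make-up the median was -0.18, which decides nothing because the clusters were made with these genes: fewer macrophages in an interferon state and a lower level in every macrophage could both give it. Effects of tamoxifen and of depletion could not be told apart in this design, and neither was tested.

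Myofiber barcodes could be pieces of fibers without a nucleus, although per the labels the sort had gates against debris. The median mitochondrial share of these barcodes, 0.0503%, was below the 0.328% of neutrophils, and what it means for fiber pieces was not tested. At 1000 UMIs each, 13.2% of myofiber barcodes held a UMI of the nuclear RNA Malat1, against 91.3% in the lowest other class, as such pieces would give. A nucleated fiber with abundant fiber RNA could also give a low share at a fixed depth. The test therefore does not decide whether myofiber barcodes had a nucleus. Mixed free RNA of all cells in droplets without a cell does not account for them: it would raise collagens along with myofiber genes, yet the mean UMIs of 3 collagens were at most 4.45 times those of neutrophil barcodes in a library. Free RNA of myofibers alone stays open, since their 670 times higher median of myofiber UMIs than in neutrophil barcodes follows from naming the class by these genes. No biological explanation for their share was tested.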

How the results depend on the processing

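Over 161 values and all alternatives, 2045 comparisons stayed the same, 110 were stronger, 111 weaker, 48 moved and 51 reversed. With an estimated correlation or fry 0 comparisons stayed the same, 0 lists were called in fibrogenic cells, macrophages and endothelial cells, and 26 list calls were lost under each. Both draw on the few degrees of freedom left by the libraries and could hardly call a list, so these losses decide little. No filter made 57 results stronger, DESeq2 16 and the block 12. For what follows the cause was not tested unless stated.

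Genes called with no filter on low counts numbered 238 (fibrogenic), 333 (macrophages), 65 (endothelial), 153 (other classes) and 29 (interaction); only 23, 27 and 25 of those in the first 3 classes were genes that the filter had left out. DESeq2 called 14, 65, 2, 12 and 23. Equal cells and depth gave 1 gene in fibrogenic cells. The stricter cell filter gave 3 in other classes and 1 in the interaction, and doublets kept gave 0 and 3. The same cluster make-up, chosen after seeing the data, gave 2 genes in fibrogenic cells; in endothelial cells, a single cluster, it only drew 34 cells per library and gave 1. Lists called fell to 2 (fibrogenic) and 4 (endothelial) without genes prone to come from other cells, where fewer genes are tested, and to 7 (fibrogenic) without barcodes rich in immune markers.

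The labels give the groups shared replicate numbers without saying what they mark. Same-numbered libraries correlated in their deviations from the group mean at 0.20 (fibrogenic), 0.036 (macrophages), 0.13 (endothelial), 0.040 (T and NK), 0.096 (dendritic), 0.18 (myofiber barcodes) and -0.045 (neutrophils). With the replicate number as a block, 53 genes were called in fibrogenic cells and 26 in other classes, and the endothelial share turned to -0.0278.

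Leaving out each library in turn, where a lone library is assumed to vary like the others, gave 0 to 5 genes in fibrogenic cells, 0 to 87 in macrophages, 1 to 17 in endothelial cells, 84 to 110 in other classes and 0 to 63 in the interaction. Lists called ranged from 6 to 16 in macrophages and from 7 to 13 in endothelial cells. In fibrogenic cells complement ranged from -0.29 to 0.13, glycolysis from -0.0132 to 0.21 and neutrophil genes from -0.92 to 0.37. In endothelial cells stress genes ranged from -0.0704 to 0.68 and myofiber genes from -1.71 to 0.14. Shares ranged from -1.26 to 1.12 (endothelial), -0.60 to 0.47 (glial), -0.25 to 0.0073 (macrophage), -1.02 to 1.63 (mural) and -0.14 to 1.70 (tenocyte). Fibrogenic Col12a1 ranged from -0.44 to 0.0045, Lrg1 from -0.12 to 1.40, Pfkfb3 from -0.015 to 0.59, Camp from -1.66 to 0.64 and Retnlg from -1.34 to 2.20. Macrophage Col4a2 ranged from -0.49 to 0.0837, and endothelial Ccn2 from -0.16 to 0.77, Plvap from -1.58 to 0.0545 and Tnnt3 from -2.24 to 0.13.

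Directions also turned elsewhere. Without genes prone to come from other cells, fibrogenic chemokines stood at 0.0905 and complement at 0.14. With doublets kept, complement stood at -0.0052 with the test pointing up, C5ar1 at 0.20, macrophage Dcn at 0.65 and endothelial Fbn1 at 0.0843. With the stricter filter, the endothelial share was -0.12, the neutrophil share 0.0461 and Pltp -0.0858. With immune cells out of the denominator the endothelial share was -0.55 and the tenocyte share -0.0228; the glial share was 0.10 with TMM scaling and 0.11 with myofiber barcodes out. Coarser clusters gave -0.10 for macrophage Mylpf, 0.18 for Dcn and -0.00854 for endothelial Ccn2. Equal depth, with 34 endothelial cells per library, gave 0.12 for Ube2c, 0.79 for Top2a and -0.14 for Selenop. The same cluster make-up gave 0.25 for macrophage Rsad2 and -0.65 for fibrogenic Retnlg; without barcodes rich in immune markers Retnlg was -0.22, Camp 0.71 and Pfkp -0.0606.

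The myogenic ratio kept its sign and stayed uncalled, from -4.15 (doublets kept) to -0.89 (without retained library 1); coarser clusters formed no myogenic class, so that setting gave no value. In simulated data of this size, 2-fold changes were found for 15.8% of genes in endothelial cells, 30.4% in T and NK cells and 1.6% in neutrophils. The absence of calls for most genes there leaves such changes open. Rates were higher in fibrogenic cells and macrophages, but the simulated genes were independent and followed the fitted dispersion trend. The absence of calls in these 2 classes therefore does not exclude large changes either.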

Other observations

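The interferon and class II lists were also tested in the smaller immune classes, where the values follow as measured. In dendritic cells interferon response genes fell by a median of 0.93 on the log2 scale (19 of 20 lower; camera, adjusted p = 5.8e-28, or adjusted p = 0.697 with an estimated correlation; 8 genes lower adjusted over the list alone), and in neutrophils by 0.99 (18 of 19 lower; adjusted p = 0.0144, or adjusted p = 0.846 with an estimated correlation). The neutrophil value rests on retained library 2: the mean list level was 107% and 56.8% of the mean of the 4 libraries in the depleted and 51.2% and 185% in the retained libraries. With the same cluster make-up, chosen after seeing the data, the neutrophil median was 0.20; dendritic cells were a single cluster, so the setting tests nothing there. Class II genes fell by 0.36 in dendritic cells (8 of 9 lower; adjusted p = 0.00755, or adjusted p = 0.697 with an estimated correlation) and by 0.72 in neutrophils (5 of 5 lower; adjusted p = 0.0148, or adjusted p = 0.846 with an estimated correlation). On the same scale the class II levels were 70.4%, 108%, 101% and 121% in dendritic cells (depleted 1 and 2, retained 1 and 2), lowest in depleted library 1 with its 39 cells. In neutrophils they were 64.0%, 96.0%, 144.5% and 95.5%, so libraries of the groups overlapped in both classes. With the same cluster make-up the class II median in neutrophils was -1.28 (5 of 5 lower). Neutrophil clusters differed in 1 library: cluster 6, led by Cxcl2, Ccl3 and Il1b, held 68.8% and 70.1% of the neutrophils of the depleted libraries and 72.0% of those of retained library 1, whereas cluster 4, led by S100a9 and Retnlg, held 88.7% of those of retained library 2.

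Glycolysis genes rose in dendritic cells by 0.42 (15 of 16 higher; adjusted p = 1.17e-05, or adjusted p = 0.697 with an estimated correlation). Cell cycle genes stood at 0.40 there (15 of 16 higher; adjusted p = 0.000944, or adjusted p = 0.697 with an estimated correlation), which rests on depleted library 1: the levels were 212%, 50.4%, 70.3% and 66.9% in the same order. Mitochondrially encoded genes fell there by 0.35 (13 of 13 lower; adjusted p = 0.00015, or adjusted p = 0.697 with an estimated correlation) and in neutrophils by 0.71 (11 of 12; adjusted p = 0.00465, or adjusted p = 0.846 with an estimated correlation). Their levels were 72.6%, 104%, 118% and 105% in dendritic cells and 75.6%, 96.5%, 130% and 98.2% in neutrophils, so depleted library 2 lay within 2 percentage points of retained library 2 in both. In all, 6 of 22 lists were called in dendritic cells, 4 of 22 in neutrophils, 6 of 22 in myofiber barcodes and 1 of 11 in T and NK cells, and 0 in each with an estimated correlation. Collagens stood at 1.04 in myofiber barcodes (8 of 8 higher; adjusted p = 4.88e-06, or adjusted p = 0.683 with an estimated correlation), with levels of 206%, 69.4%, 35.3% and 89.3%. In depleted library 1, 16 of 815 such barcodes held 81.6% of the UMIs of 3 collagens.

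Of the 16 T and NK cells with a Calca UMI, 8 carried Cd3e, 7 Gata3, 5 Il1rl1, 5 Areg and 7 Nkg7; of the 169 other cells of the class these numbers were 103, 33, 7, 15 and 104. The genes were chosen after the Calca result was seen. By library, Calca cells with Gata3 numbered 3 and 4 in the depleted and 0 and 0 in the retained libraries. Those with Il1rl1 numbered 1 and 4 against 0 and 0, and those with Areg 2 and 3 against 0 and 0. Calca cells with Cd3e (4 and 2 against 1 and 1) and Nkg7 (2 and 3 against 0 and 2) came from both groups. The pooled comparison is therefore not separate from the groups. The T and NK cell list in this class stood at 93.3% and 85.1% of the mean of the 4 libraries in the depleted libraries. In the retained ones it stood at 116% and 106%. Whether the make-up of the class differed was not tested.

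Some cell types formed no cluster. Cells with at least 3 markers numbered 11, 3, 20 and 2 for B cells, 1, 2, 16 and 3 for erythroid cells, 5, 1, 0 and 0 for lymphatic endothelial cells and 2, 0, 0 and 0 for mast cells (depleted 1 and 2, retained 1 and 2).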
